A study of Homo sapiens with 2 samples.

How the data were processed

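The study compared HaCaT cells, an established human keratinocyte line, made by retroviral transduction to carry either the TY1 epitope tag alone (TY1 control) or SNAI2 with that tag (TY1-SNAI2). Total RNA of each was extracted with a NucleoSpin RNA kit, amplified and labelled with Cy3 using Agilent's low input kit, per the labels' protocols, and each was hybridised to 1 Agilent array. The groups therefore hold 1 array each, 2 arrays in all, and both lie on the same slide.

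The deposited scanner files give spot intensity on a linear scale. Per the file headers, Feature Extraction 10.7.1.1 subtracted the background with a spatial detrend, applied a multiplicative detrend and gave dim spots a surrogate value, while the submitters' processing notes name version 9.5.1.1. The yes or no marks for spots well above background, saturated or outlying are also as deposited, per the file headers. The array design was 072363, with 60-base probes placed on genome build hg19. Each array held 62976 spots, of which 60901 were not controls, for 58201 probes.

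The authors also deposited a value table of the same 58201 probes. Its values are intensity on a linear scale, and both columns have a median of 8.60. Sorted, the columns differed by at most 0.304, which is what quantile normalization leaves. The values lay between 0.922 and 1.20 times the scanner signal for TY1 control and between 0.817 and 1.08 times for TY1-SNAI2, so they are neither logged nor centred, and the direction is that of the arrays. How the table was made is not given in the sources used here. It served as an alternative.

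For the main values, the log2 processed signal had each array's 75th percentile over the probes subtracted (102.6 in TY1 control and 133.0 in TY1-SNAI2). Control spots and spots marked as outliers (68 and 60) were left out, the spots of a probe were averaged, and no spot was saturated. Probes were named through their accession (31104 probes) or, failing that, the symbol (3366) or an older symbol (496) in a RefSeq gene table of assembly GRCh38.p14, used for names only. Another 170 kept the name in the files, and 23065 probes without a gene symbol were left out of the gene comparisons. Coordinates are those of the files, on hg19. No annotation of that build was used here, so exons and untranslated regions are not stated.

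A gene was measured when at least 1 probe was well above background on at least 1 array, and it was read by its brightest such probe. Signals were set no lower than the lowest scaled signal of a probe well above background on that array, which corresponds to a signal of 16.7 in TY1 control and 14.5 in TY1-SNAI2. Where the probe was well above background on 1 array alone, the difference is a lower bound, written as at least so many fold. The bound sets the bright signal against the higher of that floor and the dim probe's own signal. Where the difference ran against the array on which the probe was well above background, it gives no fold.

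With 1 array per group no test was made and no p-value is given. Genes are called higher or lower at 2-fold, a log2 difference of 1. For each of 26 gene lists, the median log2 difference is given with its percentile among 10000 random lists of the same size, drawn from genes of like mean level in 20 bins. That percentile describes these 2 arrays and not the cells in general. The technical error is the SD of the log2 difference over repeated spots of a probe, pooled by brightness: 0.28 for control signals under 100, 0.08 from 100 to 1000 and 0.06 above 1000. Probes with 10 spots have their own value. This error leaves out the spread between cultures, and the number of arrays limits the precision.

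The lists and the rule for named genes were fixed before the data were examined. The rule took SNAI2, then the 12 genes with the highest and the 12 with the lowest difference among those well above background and unsaturated on both arrays, leaving out names that are only a clone, locus or transcript number, XIST and Y-linked genes. It also took the 5 genes with the largest bound on either side under the same exclusions. From each list it took up to 4 members with the largest difference, and any other member that the list's account needs. Each printed difference is TY1-SNAI2 minus TY1 control.

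Alternatives were normexp background correction of the mean and local background signals with an offset of 50, quantile normalization, scaling on the median, a loess correction by brightness, only probes well above background on both arrays, no filter and no floor, the median of a gene's probes, outlier spots kept, saturated probes left out, and the authors' value table. After the data were seen, 3 were added: removal of the trend on probe GC content, reading each gene by its 3′-most probe, and counting a gene only where at least 2 probes were well above background on both arrays and all of these passed.

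The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The steps were tested on simulated data made from the levels of the TY1-SNAI2 and TY1 control arrays, over 14542 genes with a spot SD of 0.1. All 50 genes raised by 2.0 and all 50 lowered by 2.0 on the log2 scale passed 2-fold, as did 50 of 50 raised by 1.3 and 47 of 50 lowered by 1.3, and 0 of 14342 other genes did. The simulated spot SD of 0.1 is above the 0.08 and 0.06 of the brighter repeated spots. It is below the 0.28 for control signals under 100 and the 0.34 between different probes of a gene. These counts therefore do not show how often dim genes, or genes whose probes disagree, are missed or called in error. A list of 15 genes raised by 0.4 lay at percentile 100, and 1.5% of 200 random lists fell outside the middle 95%. Those 200 lists were random draws of unchanged genes with independent simulated noise. Their share therefore does not show how often lists of genes that vary together fall outside.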

Results

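Gene expression was measured on 1-colour 60-base oligonucleotide arrays in HaCaT keratinocytes expressing the TY1 tag alone (TY1 control, 1 array) or TY1-tagged SNAI2 (TY1-SNAI2, 1 array). SNAI2, also called Slug, is a zinc finger transcriptional repressor known for its part in epithelial to mesenchymal transition (EMT). The comparison addressed what overexpression of SNAI2 does to the transcriptional program of these cells. On the TY1 control array 24715 of 60901 non-control spots (40.6%) were well above background, and on the TY1-SNAI2 array 26619 (43.7%). Of 14542 measured genes, 13651 were measured on both arrays, 116 on TY1 control alone and 775 on TY1-SNAI2 alone. No difference below has a replicate check, and none was tested.

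SNAI2 was read by 1 probe with 1 spot. Its processed signal was 237.8 in TY1 control and 346.0 in TY1-SNAI2. After scaling this was a log2 difference of 0.17 (1.12-fold higher), beside a technical SD of 0.08 for spots of its brightness and a median of 0.07 over all genes measured on both arrays. Whether the probe's target lies within the transduced sequence is not known here. If it lies outside, the probe does not measure the transgene, and if it lies inside, the value does not show the overexpression that the labels give. The value therefore does not support the labels, and while the target is not known it does not contradict them either.

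The TY1-SNAI2 array differed little from its control across most genes, and the larger differences lay mainly on the lower side. In TY1-SNAI2, 22 genes were at least 2-fold higher and 149 at least 2-fold lower, together 1.18% of the measured genes. Of these, 10 higher and 87 lower genes were measured on both arrays, and the other 12 and 62 rest on a bound. The bounds are not on an equal footing, since the scaled log2 floor was -2.62 in TY1 control and -3.19 in TY1-SNAI2. A gene measured on TY1 control alone can thus reach a larger bound than a gene of the same level measured on TY1-SNAI2 alone. Over the genes measured on both arrays the log2 differences had an SD of 0.32, with 95% of them between -0.73 and 0.59, and the log2 levels correlated across genes with r = 0.993. The balance depends on the scaling. With the median in place of the 75th percentile every difference moved up by 0.19, and 93 genes were higher and 48 lower, so that the higher share went from 12.9% to 66.0%. The median non-control spot had a processed signal of 9.15 in TY1 control and 10.5 in TY1-SNAI2, below the floors of 16.7 and 14.5. Median scaling thus aligns the arrays on signals that are not well above background. With normexp background correction of the mean and local background signals and an offset of 50, 1 gene was higher and 5 were lower. The offset is added to both signals of a probe and so makes the differences of dim genes smaller. A dim gene that falls short of 2-fold with normexp is therefore not shown to be unchanged.

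**Figure D1:**
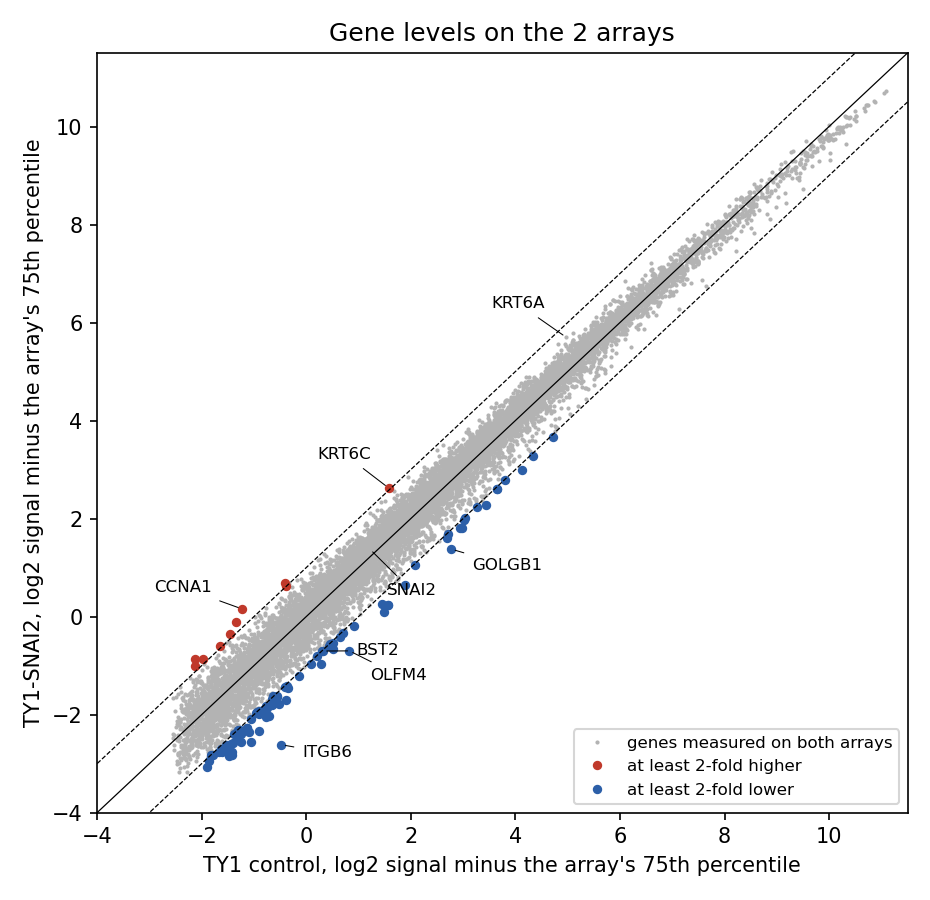
Scaled log2 level of each gene measured on both arrays, TY1 control on the horizontal and TY1-SNAI2 on the vertical axis, 1 point per gene. The solid line marks equal levels and the dashed lines 2-fold differences; 10 genes lie on or above the upper line and 87 on or below the lower one, and SNAI2 lies at 0.17 above equality.

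Among genes measured on both arrays, the highest was CCNA1, which encodes cyclin A1, at 2.61-fold higher in TY1-SNAI2 (log2 difference 1.38, technical SD 0.28; chromosome 13, 37014154 to 37014213). PLS3-AS1 followed at 2.40-fold and USP41P at 2.35-fold. PITPNM2, CHST14, KIF9-AS1 and KCNIP3 were 2.19-fold, 2.16-fold, 2.16-fold and 2.13-fold higher. KRT6C, a keratin of stressed and wounded epidermis, was 2.07-fold higher (technical SD 0.08 on the log2 scale), but it is so close in sequence to KRT6A that its probe may read both. CLK2 was 2.02-fold higher. NECAP1, CYP4F29P and IQANK1 lay just under 2-fold, at 1.998, 1.987 and 1.984, and a second NECAP1 probe read 0.11. Of these 12 genes, 11 had a single measured probe, and most were dim, with TY1 control signals under 100 for all but KRT6C. With normexp 1 of the 12 passed 2-fold, but its offset by itself makes the differences of such dim genes smaller.

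Among genes measured on both arrays, the lowest was ITGB6, which encodes the integrin β6 subunit of epithelial cells, at 4.40-fold lower in TY1-SNAI2 (log2 difference -2.14, technical SD 0.28; chromosome 2, 160958330 to 160964233, a span longer than the probe's 60 bases). OLFM4, a secreted glycoprotein, was 2.86-fold lower (log2 difference -1.51, technical SD 0.08) and STRN3 was 2.82-fold lower. NADK2, the mitochondrial NAD kinase, was 2.63-fold lower and APC, a negative regulator of Wnt signalling, was 2.5-fold lower. TFDP3, SNORD41, TRIM61 and SLC9A9 were between 2.49-fold and 2.60-fold lower. CNTNAP3, GOLGB1 and PDCD6IP were 2.70-fold, 2.63-fold and 2.52-fold lower by the brightest probe. Other probes of these 3 genes did not match, with log2 differences of up to 0.53 for CNTNAP3, 0.08 for GOLGB1 and -0.19 for PDCD6IP. The other genes named here had a single measured probe. ITGB6, STRN3, CNTNAP3, TFDP3, SNORD41, TRIM61 and SLC9A9 were dim, with TY1 control signals under 100. ITGB6 had a signal of 73.6 in TY1 control and 21.7 in TY1-SNAI2, where the floor was 14.5. The technical SD of 0.28 for such signals rests on 10 probes.

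Of genes not well above background in TY1 control, SPINK6, a skin inhibitor of kallikrein proteases, was at least 2.78-fold higher in TY1-SNAI2. USP46-DT, FAM219B, ASB8 and PSMD6-AS2 were at least 2.30-fold, 2.27-fold, 2.24-fold and 2.16-fold higher. Of genes not well above background in TY1-SNAI2, the homeobox gene ALX1 was at least 3.46-fold lower, WFDC21P at least 3.11-fold, SLC39A5 at least 2.9996-fold, OR2AG2 at least 2.99-fold and the homeobox gene HOXB7 at least 2.85-fold. All 10 had faint signals, at most 60.2 on the brighter array.

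Different probes of a gene often differed. Over 3699 genes with several probes measured on both arrays, the SD of the log2 difference between probes of a gene was 0.34, against 0.09 between repeated spots of a probe. Of the lower genes, 19 had another probe measured on both arrays, and these other probes were at least 2-fold lower for 1 gene, lower by less for 12 and not lower for 6. None of the higher genes had one. BST2 was the 1 gene for which all of several probes passed 2-fold. Probes nearer the 5′ end of a gene were lower more often. Over 3600 genes the 5′-most probe lay 0.09 below the 3′-most in the median (95% bootstrap interval over genes -0.10 to -0.07, which treats genes as independent), and it was lower by 1 or more in 188 genes and higher by 1 or more in 27.

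Genes of keratinocyte terminal differentiation had a median below that of random lists in TY1-SNAI2. Of 13 measured genes in the terminal differentiation list, 10 lay below 0 and none passed 2-fold, with a median log2 difference of -0.24 at percentile 0.59 of random lists. Among those below 0, KRTDAP read -0.03 although its probe was well above background in TY1-SNAI2 alone, so its sign is not informative. The calcium-binding protein CALML5 read -0.50, the cornified envelope precursor IVL -0.46, SBSN -0.49 and the suprabasal keratin KRT1 -0.43, while its partner KRT10 read 0.22. CALML5 and SBSN were dim, with TY1 control signals of 71.8 and 19.5 beside a floor of 16.7, and a technical SD of 0.28. The list stood outside the middle 95% of random lists in 9 of the 10 alternatives that could change a list's percentile, the exception being no filter and no floor (percentile 15.3). Here and below, the 10 are not separate checks. Quantile normalization and the authors' value table gave nearly the same percentile (0.34 and 0.40 here), and keeping outlier spots changed little (0.51). Its distance from 0 depends on the scaling: with median scaling the median was -0.050, and 7 of the 13 genes lay below 0.

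In the desmosome list, 2 of 12 genes were at least 2-fold lower, the desmosomal cadherins DSC3 (2.24-fold) and DSC2 (2.04-fold), and none was higher. In each, a second probe read nearer 0, at -0.05 for DSC3 and -0.15 for DSC2, and neither passed 2-fold with median scaling (-0.97 and -0.84), normexp (-0.94 and -0.76), the median of a gene's probes (-0.61 and -0.59) or the 3′-most probe. PKP1 read -0.39 and PPL 0.30. The list's median of -0.11 (percentile 2.46) turned to 0.08 with median scaling and 0.04 with normexp, and it was no longer outside in 5 of 10 alternatives. The hemidesmosome and basal keratinocyte list had no gene at 2-fold and a median of -0.10 (percentile 2.48), which turned to 0.09 with median scaling and 0.02 with normexp, and it was no longer outside in 3 of 10 alternatives. Its members included the integrin subunit ITGB1 at -0.79 (technical SD 0.10 over 10 spots), the basal transcription factor TP63 at -0.66, KRT15 at -0.52, KRT5 at -0.27, KRT14 at 0.02 and LAMA3 at 0.33, whose other probe read -0.24. In the list of simple and stress-associated keratins none of 9 genes passed 2-fold. KRT6A was 1.65-fold higher, and KRT4, KRT13 and KRT19 read -0.67, -0.37 and -0.36. Its median of -0.16 (percentile 2.05) turned to 0.03 with median scaling and lay at 0.00 with quantile normalization (percentile 35.7) and in the authors' value table (35.8), and it was no longer outside in 5 of 10 alternatives.

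Of markers of EMT, none passed 2-fold. Of 27 genes of epithelial identity and cell junctions, none passed 2-fold, 13 lay above 0 and 14 below, and the median was 0.00 (percentile 4.68). E-cadherin, encoded by CDH1, read -0.03 (technical SD 0.03 over 10 spots) and EPCAM read 0.30. The tight junction gene CLDN1 was 1.72-fold lower (log2 difference -0.78, technical SD 0.06), the membrane protease gene PRSS8 read -0.53, and the epithelial splicing factor ESRP2 and the transcription factor GRHL1 read 0.37 and 0.33. With median scaling CDH1 read above 0, the list's median was 0.19 and 23 of the 27 genes lay above 0. After the loess correction the list lay outside, at percentile 1.98, as in none of the other 9 alternatives. Of 16 mesenchymal genes none passed 2-fold, and the median was -0.01 (percentile 11.3), or 0.18 with median scaling, where 10 genes lay above 0. VIM, which encodes vimentin, read 0.03 at a faint signal of 35.3 in TY1 control. N-cadherin, encoded by CDH2, read 0.00, and its other probe -0.39. Fibronectin, encoded by FN1, read -0.68, TPM1 0.74, MMP2 0.63 and S100A4 -0.41, with TPM1 probes from 0.14 to 0.74. FN1 had 1 measured probe, whose distance from the 3′ end is not known here, and probes nearer the 5′ end were lower more often. MMP2 was dim, with a TY1 control signal of 78.3 (technical SD 0.28). Among 7 measured EMT transcription factors the median was 0.09 (percentile 61.9), with SNAI3 at 0.21, TWIST2 at 0.09, KLF8 at -0.07 and SOX9 at -0.10. SNAI1 was not well above background in TY1 control and was at least 1.27-fold higher.

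**Figure D2:**
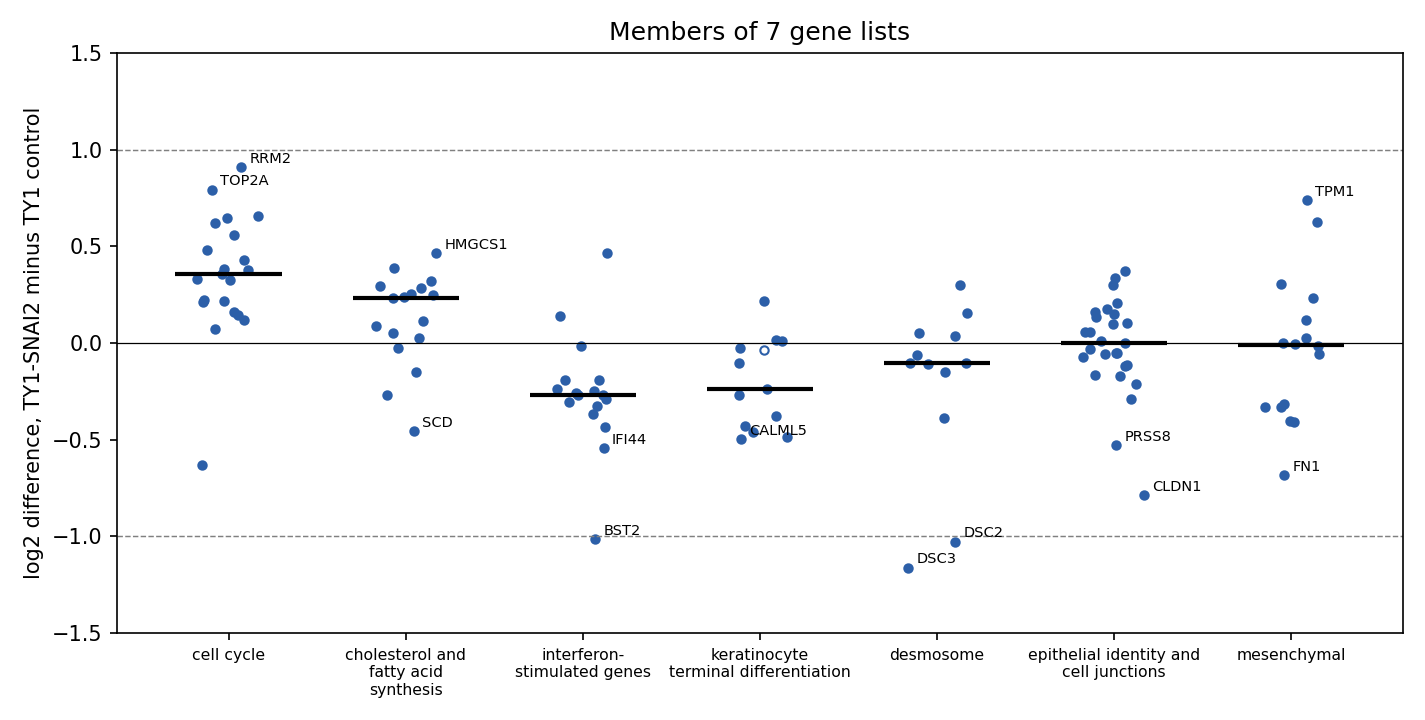
Log2 difference (TY1-SNAI2 minus TY1 control) of each measured member of 7 gene lists. Filled points were measured on both arrays and open points on 1, bars are list medians and dashed lines mark 2-fold; the cell cycle bar lies at 0.36, the interferon bar at -0.27 and the epithelial and mesenchymal bars at 0.00 and -0.01.

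Cell cycle genes were higher in TY1-SNAI2 as a group. Of 21 genes, 20 lay above 0, none passed 2-fold, and the median log2 difference was 0.36 at percentile 100 of random lists. The ribonucleotide reductase subunit RRM2 was 1.88-fold higher, topoisomerase gene TOP2A 1.73-fold, the mitotic kinase gene PLK1 1.58-fold and CCNE2 1.56-fold. CCNB1, CCNA2 and CDK1 read 0.38, 0.22 and 0.21. MKI67 was the exception at -0.63, and its 3 probes disagreed, from -0.75 to 0.64, as did those of RRM2, from -0.41 to 0.91.

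Interferon-stimulated genes were lower as a group. Of 17 genes, 15 lay below 0 and 1 passed 2-fold, with a median of -0.27 at percentile 0.03. BST2, which encodes the antiviral protein tetherin, was 2.02-fold lower and its second probe read -1.22. IFI44 read -0.55, OASL -0.44, IFIT1 -0.37 and ISG15 -0.27, while OAS1 read 0.46 at a dim TY1 control signal of 58.6 (technical SD 0.28). The cell cycle and interferon lists stood outside the middle 95% of random lists, on the same side, in all 10 alternatives that could change a percentile. The interferon median was nearer 0 with median scaling, at -0.082, and with normexp, at -0.16, and BST2 then read -0.83 and -0.65, short of 2-fold.

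In cholesterol and fatty acid synthesis, 13 of 17 genes lay above 0, none passed 2-fold, and the median was 0.23 (percentile 99.6). HMGCS1, SQLE and LSS of the cholesterol pathway read 0.46, 0.39 and 0.32, and the fatty acid desaturase gene SCD read -0.46. The percentile was 70.4 with the median of a gene's probes and 71.7 with the 3′-most probe, and the list was outside in 5 of 10 alternatives. In the Notch pathway list, 6 of 13 genes lay above 0 and 7 below, with a median of -0.23 (percentile 0.27). HES5 was at least 2.17-fold lower, but short of 2-fold with median scaling (-0.93) and normexp (-0.45). The coactivator gene MAML2 read -0.88, HES2 -0.34, HES1 0.33 and the ligand gene JAG2 0.46, with JAG2 probes from -0.03 to 0.71. HES5, MAML2 and HES1 were dim, with TY1 control signals under 100 (technical SD 0.28). The Notch median turned to 0.12 with the median of a gene's probes and to 0.15 with the 3′-most probe, and it was -0.039 with median scaling. The list was no longer outside in 4 of 10 alternatives, among them probes well above background on both arrays (percentile 6.40).

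**Figure D3:**
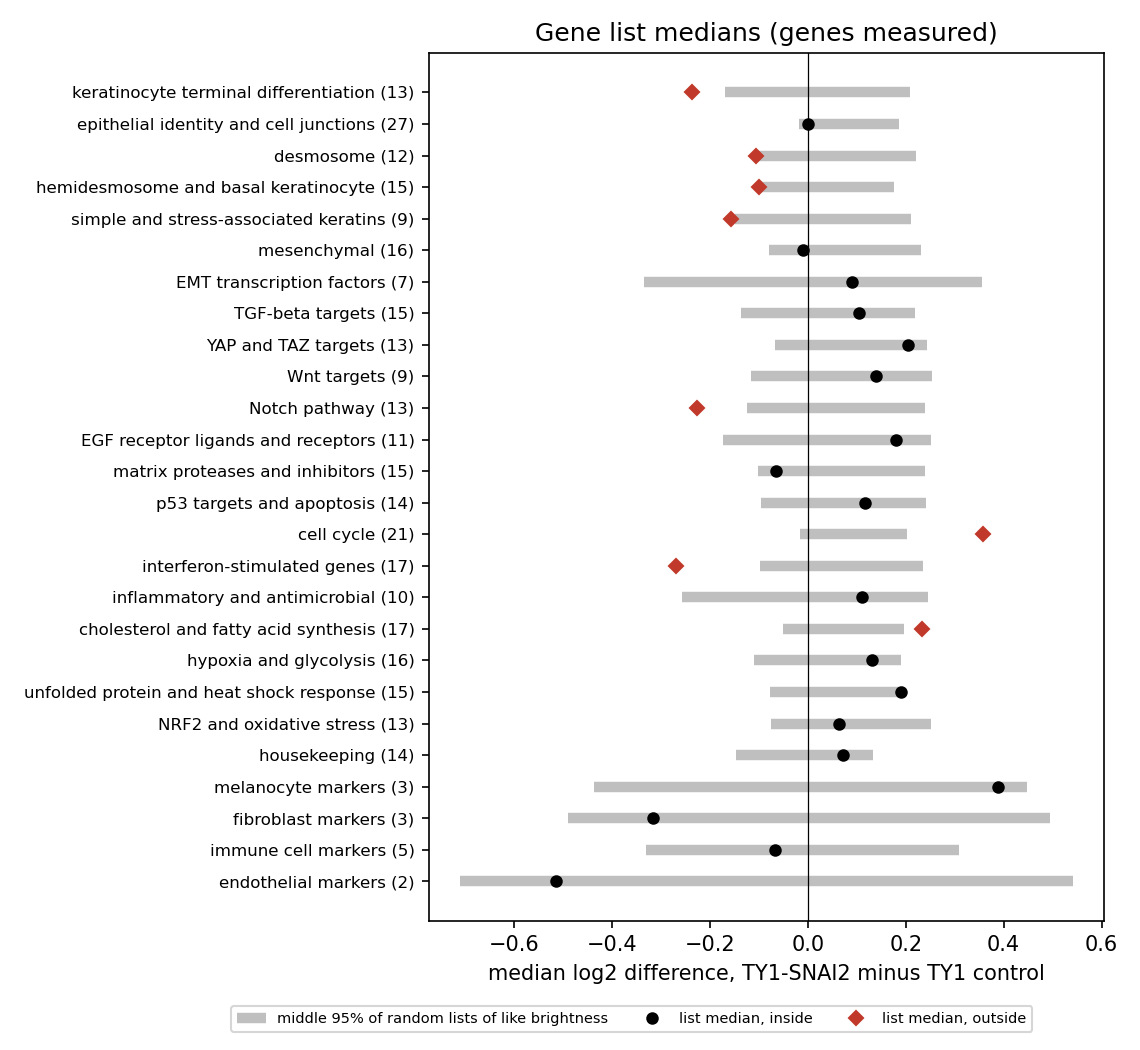
Median log2 difference (TY1-SNAI2 minus TY1 control) of 26 gene lists, with the number of measured genes in brackets. Grey bars hold the middle 95% of medians of 10000 random lists of like brightness; 8 lists lie outside (diamonds), of which cell cycle at 0.36 and interferon at -0.27 are the farthest from their bars.

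Of the 26 lists, 8 stood outside the middle 95% of random lists, where 1.3 would do so by chance if lists behaved as random ones. Lists of genes that vary together need not behave so, and for them the 1.3 is no guide. The desmosome (percentile 2.46) and hemidesmosome and basal keratinocyte (2.48) lists lay at the edge of 2.5. Both were within 0.31 of it, the 95% half-width of a percentile near the edge. The random draws therefore do not decide whether these lists lie outside. The other signalling lists lay inside. TGF-β targets had a median of 0.10 (percentile 71.9), with SMAD7 at 0.35, ID2 at -0.37, whose second probe read 0.15, and TGFB2 at -0.43. Targets of YAP and TAZ had a median of 0.20 (percentile 92.7), and lay outside with quantile normalization (97.9) and in the authors' value table (97.9). CCN1, AJUBA and F3 read 0.56, 0.48 and 0.46, and PTPN14 read -0.85 with other probes up to 0.13. Wnt targets had a median of 0.14 (percentile 72.6), with the Wnt inhibitor DKK1 at 0.54, CCND1 at 0.28 and WNT10A at -0.27. In the list of EGF receptor ligands and receptors (median 0.18, percentile 88.1), the ligand HBEGF was at least 2.10-fold higher and the ligand BTC was 2.11-fold lower. With normexp neither passed 2-fold (0.16 and -0.55), and with median scaling BTC did not (-0.89). HBEGF and BTC were dim, with TY1 control signals under 100 (technical SD 0.28). The feedback inhibitor ERRFI1 read 0.61, AREG 0.31 and EGFR 0.06, with EGFR probes from -0.55 to 0.50.

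Inflammatory and antimicrobial genes went both ways, with a median of 0.11 (percentile 78.6). CXCL1 was 1.86-fold higher, IL1B 1.78-fold and CXCL2 1.54-fold, CCL2 read -0.73 (technical SD 0.12 over 10 spots), and LCN2 was at least 1.84-fold lower. Over probes well above background on both arrays alone, this list lay at percentile 99.7, and with the median of a gene's probes at 99.0. Matrix proteases and their inhibitors had a median of -0.06 (percentile 5.52), with TIMP3 at -0.66, MMP10 at -0.55, MMP1 at -0.52 and the urokinase receptor gene PLAUR at 0.41. For p53 targets and apoptosis the median was 0.12 (percentile 65.5), with BCL2L1 at 0.56, CDKN1A at 0.36 and PMAIP1 at -0.36. Of the genes named so far in this paragraph, CXCL2, LCN2, MMP10 and CDKN1A were dim, with TY1 control signals under 100 (technical SD 0.28). Hypoxia and glycolysis genes had a median of 0.13 (percentile 85.5), with ADM at 0.45, ANKRD37 at 0.45, and VEGFA at -0.81 by its brightest probe and 0.53 by the other. Unfolded protein and heat shock genes had a median of 0.19 (percentile 96.7), with HSPA1A at 0.38, ATF3 at 0.31 and XBP1 at 0.27. NRF2 and oxidative stress genes had a median of 0.06 (percentile 33.6), with SLC7A11 at 0.38 and TXNRD1 at -0.62.

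Housekeeping genes had a median of 0.07 (percentile 83.5), beside 0.07 over the genes measured on both arrays, with TFRC at 0.43, GAPDH at -0.09 and ACTB at -0.20. With median scaling the housekeeping median was 0.26. Few markers of other cell types were measured. The medians were 0.39 over 3 melanocyte markers (percentile 94.5), -0.32 over 3 fibroblast markers (percentile 8.33), -0.07 over 5 immune cell markers (percentile 26.5) and -0.51 over 2 endothelial markers (percentile 7.91). The melanocyte list lay outside with the 3′-most probe (percentile 98.1), and at 38.0 over probes well above background on both arrays and 23.1 with no filter and no floor. MITF read 0.39, with probes from -0.76 to 0.48, COL1A1 -0.32, CD14 0.07 and VWF -0.61. COL1A1 and VWF were dim, with TY1 control signals under 100 (technical SD 0.28). PTPRC, an immune cell marker chosen after its values were seen, was faint in TY1 control and at least 2.12-fold lower, but short of 2-fold with quantile normalization, loess and the authors' value table (each -0.98), median scaling (-0.90) and normexp (-0.32).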

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

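These values come from probes without a gene symbol, which the gene comparisons did not use, and stand out because their signal on the TY1-SNAI2 array was more than 4-fold above the control array. The probe named lnc-EFR3B-4 in the files (chromosome 2, 25650374 to 25650433, plus strand, hg19) was not well above background in TY1 control, at a processed signal of 4.18, and read 173 in TY1-SNAI2, a log2 difference of at least 2.999 (at least 7.99-fold). The probe named THC2507047 (chromosome 2, 216226694 to 216226753, plus strand) was measured on both arrays, at 26.0 and 185, a log2 difference of 2.46 (5.50-fold). It starts 61523 bases from the start of the array's FN1 probe, which lies on the opposite strand and read 214 and 173. Each has 1 spot per array, and neither a technical nor a biological explanation was tested.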

How the results depend on the processing

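Removal of the GC trend, the 3′-most probe and the rule on several probes were chosen after seeing the data. No paired analysis was possible because each group has 1 array, and for that reason no array could be left out. The signal over background limits the genes that rest on a bound, and the cause of the moves below was not tested unless named. Among 12 alternatives, SNAI2 stayed between 0.09 and 0.21, except 0.35 with median scaling. The counts of 22 higher and 149 lower genes stayed within 1.5 times under quantile normalization, loess, the median of a gene's probes, outlier spots kept, the authors' value table, the GC correction and the 3′-most probe, at 22 to 32 higher and 120 to 157 lower. Leaving out saturated probes removed none. The counts were 1 and 5 with normexp, whose offset makes the differences of dim genes smaller. They were 93 and 48 with median scaling, which rests on signals not well above background. They were 10 and 87 over probes well above background on both arrays, which drops the bounds, and 511 and 1457 with no filter and no floor, which admits background probes. Where several probes all had to pass they were 0 and 1. Of the 12 highest genes 9 passed 2-fold, or 1 under normexp, 8 with loess, 10 with quantile normalization, 11 in the authors' value table and 12 with median scaling. The 12 lowest genes all passed 2-fold except under normexp (3 of them), the median of a gene's probes (9) and the 3′-most probe (9).

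List medians moved by less than the SD of random lists in 248 cases and by more in 55. In 9 others, all of lists outside the middle 95%, they changed sign or fell to 0, and 11 of the first 2 kinds, in the remaining lists, changed sign as well. With median scaling, which adds 0.19 to every difference and leaves percentiles as they were, they were -0.050 for terminal differentiation, 0.19 for epithelial, 0.081 for desmosome, 0.087 for basal, 0.029 for keratins, 0.18 for mesenchymal, 0.28 for EMT factors, 0.29 for TGF-β, 0.39 for YAP and TAZ, 0.33 for Wnt, -0.039 for Notch, 0.37 for EGF receptor, 0.12 for proteases, 0.30 for p53, 0.54 for cell cycle, -0.082 for interferon, 0.30 for inflammatory, 0.42 for cholesterol, 0.32 for hypoxia, 0.38 for unfolded protein, 0.25 for NRF2, 0.26 for housekeeping and 0.12 for immune. With normexp they were -0.12 for terminal differentiation, 0.14 for epithelial, 0.036 for desmosome, 0.021 for basal, -0.033 for keratins, -0.12 for Notch, 0.047 for proteases, 0.46 for cell cycle, -0.16 for interferon, 0.27 for unfolded protein, 0.18 for housekeeping and 0.092 for melanocyte.

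Quantile normalization gave -0.057 for epithelial, 0.00 for keratins, 0.28 for cell cycle and 0.14 for cholesterol, and the authors' value table -0.056, 0.00, 0.29 and 0.14. Loess gave -0.081 for epithelial, 0.30 for cell cycle, 0.16 for cholesterol, 0.048 for hypoxia and 0.10 for unfolded protein. Over probes well above background on both arrays, the medians were -0.060 for Notch, 0.060 for EGF receptor, 0.37 for inflammatory and 0.016 for melanocyte. With no filter and no floor they were -0.32 for mesenchymal, 0.047 for EGF receptor, -0.12 for inflammatory and -0.54 for melanocyte. The median of a gene's probes gave 0.12 for Notch, 0.058 for EGF receptor, 0.27 for inflammatory and 0.11 for cholesterol. The 3′-most probe gave 0.056 for epithelial, 0.15 for Notch and 0.11 for cholesterol, and the GC correction -0.11 for Notch. Of named genes, CNTNAP3 turned to 0.53 and GOLGB1 to 0.082 with the 3′-most probe. Other named values moved by more than the technical SD in 423 cases and by less in 1478.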

Other observations

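All tests in this part on LINC00492, on probe GC content and on the gene lists were chosen after the result was seen. Of 4552 measured probes without a gene symbol, 12 were at least 2-fold higher and 92 at least 2-fold lower in TY1-SNAI2, or 52 and 33 with median scaling. The farthest of them was lnc-GDI2-1 (chromosome 10, 5754243 to 5754302), which read 291 in TY1 control and was at least 26.0-fold lower in TY1-SNAI2. Of the others, which like it were chosen after their values were seen, XLOC_l2_002729 was at least 10.1-fold and XLOC_l2_012415 at least 4.10-fold lower. Over all 24414 measured probes, 61 were higher and 384 lower, or 235 and 132 with median scaling.

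The largest difference of any probe was that of LINC00492, a long noncoding RNA which the naming rule leaves out and which was chosen after its values were seen. Its probe (chromosome 5, 101917211 to 101917270) had a processed signal of 6833 in TY1 control and 3.40 in TY1-SNAI2, at least 610-fold lower. A second LINC00492 probe, at 101953219 to 101953278, was not well above background on either array, at 4.30 and 3.75. An uneven blemish on the spot is argued against, since the spot was not marked as an outlier and its pixel variation of 5.38% lay at percentile 5.26 among 475 spots of like brightness. What the probe read in the control cells stays open, including a transcript that differs between the 2 cell populations, and was not tested.

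Probes of a gene often disagreed. In 115 pairs a probe was at least 2-fold lower in TY1-SNAI2 while another probe of the gene was not, here meaning a log2 difference above -0.5 (median log2 differences -1.14 and -0.01). In 14 pairs a probe was higher while another was not. With median scaling these counts were 39 and 51. Dim spots as the whole cause are argued against, since 33.9% of the lower probes (95% Wilson interval 25.9 to 43.0) were in the dimmest 25% on the control array, below the 50% set beforehand, and 64 had control signals of at least 100; 99 were dimmer than the other probe, which was chosen as the brightest. The lower probe lay 5′ of the other in 89.6% of the pairs (interval 82.6 to 93.9), against 71.3% (62.5 to 78.8) for as many probes at the upper end, which is consistent with signal lost away from the 3′ end on the TY1-SNAI2 array, as from RNA of lower integrity or shorter amplified RNA. Probe GC content stays open, because the lower probe was 5.0 percentage points richer in G and C in the median, with a bootstrap interval of 3.33 to 6.67. A change of transcript ends or splicing with SNAI2 was not tested, and with 1 array per condition it stays open beside the quality of 1 RNA sample.

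Cell cycle genes had a higher median, and interferon-stimulated and terminal differentiation genes a lower one, than random lists. A brightness trend between the arrays as the whole cause is argued against: after the loess correction the 2 lists of cell cycle and interferon genes lay outside the middle 95% of random lists drawn whatever their brightness, as did terminal differentiation (percentile 0.08) and Notch (0.20), while cholesterol lay at 96.95, which leaves it open. A probe GC trend between the arrays is argued against for the cell cycle and interferon lists, both outside after its removal, and stays open for terminal differentiation (2.31, its median going from -0.24 to -0.17), Notch (2.53, from -0.23 to -0.11) and cholesterol (97.73), all within 0.31 of the edge, the 95% half-width of such a percentile. Reading each gene by its 3′-most probe left the 2 lists of cell cycle and interferon genes outside and terminal differentiation at 0.95. Few members were then read by another probe (3 of 21, 2 of 17 and 1 of 13). Probes far from the 3′ end therefore stay open for cell cycle, interferon and terminal differentiation genes. Lost signal lowers the probes it affects, but values were scaled to each array and ranked against other genes. Loss at other genes could thus raise the cell cycle list relative to them. Its higher median, 0.36 with either choice of probe, therefore does not decide. Notch moved to 80.4 (median from -0.23 to 0.15, SD of random lists 0.09), the move set for this explanation, although 2 of 13 members changed probe. That move does not decide, because the list has a gap between NRARP at -0.23 and LFNG at 0.11. NOTCH1, with probes at -0.27 and 0.56, can carry the median across it. Cholesterol moved to 71.7 by a fall (from 0.23 to 0.11), which lost signal does not account for, so for it the choice of probe stays open. An effect of SNAI2 itself on these lists was not tested and stays open, as does any difference between the cultures, since there was 1 culture of each kind.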
